A study of Drosophila melanogaster with 8 samples.

How the data were processed

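Wing imaginal discs of Drosophila larvae with MARCM clones were dissociated for 10 min and profiled as 10x Genomics single-cell RNA libraries, 1 library per file. The 8 libraries fall into 5 groups: control (1), scrib (2), scrib NAct (2), scrib RasV12 (2) and scrib YkiS168A (1). About 50 embryos were collected within 3 h, and larvae were heat-shocked at 37 °C for 1 h at 60 h and dissected at 96 h after egg laying, per the labels. The labels do not say whether libraries of a group come from separate animals or days.

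Reads were processed with Cell Ranger and Seurat, per the submitters' processing notes, which give no versions. The genome build is not given in the sources used here, and 85.1% of the 9306 gene symbols (7918) are in the annotation at hand, so genes are named by the symbols of the files and no coordinates are given. The deposited values are natural log values, ln(1 + UMIs per 10000 UMIs of the cell). Taken back to the linear scale they are whole multiples of the smallest value of each cell (100% of values, tolerance 0.01), which gave the whole UMI counts. The deposited cells had been filtered: no cell lay above 49996 UMIs or below 6049, none had fewer than 1501 genes, no mitochondrially encoded gene was listed, and each listed gene was seen in at least 5 cells. No doublet caller was run, and no cell was removed. Files list 8077 to 8917 genes, 7886 of them in all 8.

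Total depth ran from 46117958 to 169428051 UMIs per library, median depth from 17582.5 to 26974 UMIs per cell and median genes per cell from 2726.5 to 3332. Shares of cells carry exact (Clopper-Pearson) 95% intervals, and a count of 0 was read as allowing up to 3 counts.

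Cells were clustered with scanpy 1.11.5 (2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 1, with 2 as an alternative). GFP, Gal80, roX1 and roX2 were left out of the clustering. The 23 clusters were named from 9 marker lists. A cluster with at least 3 markers of another class raised by a log2 of 1 took that class if trh and btl (trachea) or twi and htl (muscle precursors) were each seen in 25% of its cells and, outside trachea, its 10 leading genes held at least 1 marker of that class and no more of another. Otherwise it stayed unnamed. Any other cluster was epithelial-like if at least 8 epithelial markers were each seen in 25% of its cells and its leading genes held no more markers of another class. This left 4 clusters unnamed. Neither cluster markers nor cluster sizes were tested between groups.

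For each library the mean over its epithelial-like cells of UMI counts per-million (CPM) was taken, and log2(mean + 1) of 6065 genes with a mean of at least 5 CPM was fitted with limma 3.58.1 in R 4.3.3 (variance trend, Benjamini-Hochberg adjusted p under 0.05, two-sided). A single fit over the 8 libraries, with 3 residual degrees of freedom, compared scrib with control and each of the other 3 genotypes with scrib, so the lone control and scrib YkiS168A libraries were assumed to vary like the pairs. Clone cells were epithelial-like cells with at least 1 GFP UMI. Their log2 difference from cells with none was taken within each library and tested against 0 per genotype with limma. Of 28 gene lists, 26 with at least 5 tested members were tested with camera (correlation 0.01), with an estimated correlation and fry as alternatives. Lists can share members, as the JNK and stress response list and the Yorkie target list share Ilp8, so their calls are not independent. These comparisons, the lists and their tests between genotypes, the alternatives and the rule for named genes were chosen before the data were examined.

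By that rule the text names, per comparison, up to 8 rises and 8 falls with the largest log2 change among genes past the test that moved the same way in every pair of libraries, leaving out gene models known only by a CG or CR number. Where fewer passed, genes with the lowest p, up to 4 each way, are given as values. From each list described, 2 to 4 members are named, and the drivers scrib, N, Ras85D and yki are given in every library, with their tests.

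Alternative settings covered the pseudocount, the filter on low values, the library summary, centring and quantile normalization, all cells, cluster resolution, the variance model, the replicate block, thinning of cells to 2000 UMIs, the GFP threshold and leaving out each library of a pair. Added after seeing the data were a batch term for whether the file lists Gal80, fits without the low-UMI clusters (median under 15000), without the GFP-rich cluster or with the unnamed clusters, comparators matched on UMIs or on cluster and UMIs (5 per clone cell), comparators with a Gal80 UMI (in the 6 libraries that list Gal80, with a fit of those 6 as their reference), leaving out libraries in the clone comparisons, list tests in the clone comparisons, and tests of whether clone differences differ between genotypes, for which 4 genes each way are named. Replicate numbers do not pair the libraries: deviations of numbered libraries correlated at -0.01, -0.23 and -0.01 across genes, which are not independent replicates.

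The fits were tested on simulated data with 200 of 6065 genes changed. The noise was normal, independent between genes and libraries, and had the fitted spread of each gene in every library. It held no split such as that between scrib 1 and scrib 2, so the rates below apply only under these assumptions. A log2 change of 1 was found in 80% to 94% of cases in the genotype comparisons and 86% to 100% in the clone comparisons, a change of 0.5 in 20% to 43% and 45% to 77%, and 3.6% to 9.3% of calls were wrong. The pairs of libraries of a genotype were not copies of each other (chi-square per degree of freedom 290.4, 6.1 and 9.6 for scrib, scrib NAct and scrib RasV12). Other software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, anndata 0.12.19, python-igraph 0.11.9 and matplotlib 3.10.9.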

Results

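Single-cell RNA profiles were made from wing imaginal discs, the larval tissue that forms the adult wing and notum, of Drosophila larvae carrying mosaic clones. The clones were made with MARCM, in which a heat-shock-driven recombinase yields cells homozygous for a chromosome arm that, at the same time, lose the Gal4 inhibitor Gal80 and so begin to express GFP and any UAS transgene. Scribbled (scrib) encodes a protein of the basolateral polarity complex, and scrib mutant clones in a normal epithelium are a standard model of cell competition. The 5 genotypes were control clones (1 library), scrib clones (2 libraries) and scrib clones that also expressed activated Notch (scrib NAct, 2 libraries), activated Ras (scrib RasV12, 2 libraries) or an activated form of the Hippo pathway effector Yorkie (scrib YkiS168A, 1 library). Discs were taken 96 h after egg laying, 36 h after clone induction, at which time clones covered about 30% of the disc area, or about 20% for scrib alone, per the series' design text. The study asked what the 3 oncogenic signals change in scrib clones at this early stage.

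The files held 35253 cells. The control library had 5430 cells and 106836578 unique molecular identifiers (UMIs). The scrib libraries 1 and 2 had 3269 and 7038 cells with 77367077 and 169428051 UMIs. The scrib NAct libraries had 2816 and 1735 cells with 63853931 and 46117958 UMIs, and the scrib RasV12 libraries 4187 and 3512 cells with 85062332 and 76584231 UMIs. The scrib YkiS168A library had 7266 cells with 143067308 UMIs. Median UMIs per cell lay between 17582.5 and 26974.

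Disc epithelium made up most of every library. Epithelial-like clusters held between 78.9% (scrib YkiS168A) and 85.6% (scrib NAct 2) of cells, adult muscle precursor-like clusters, marked by twi and htl, between 4.42% and 7.95%, and a tracheal-like cluster between 0.058% and 0.534%. The other cells, between 7.9% and 14.1% of a library, lay in 4 clusters that the fixed markers did not name. Comparisons below use the epithelial-like cells.

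The control library and scrib library 1 stood apart from the other 6. Control 1 and scrib 1 differed by a root-mean-square log2 difference of 0.176 over 6065 genes, whereas scrib 1 differed from scrib 2, of the same genotype, by 0.395. The scrib NAct pair differed by 0.099 and the scrib RasV12 pair by 0.086. The files of control 1 and scrib 1 also list no Gal80 row, which the other 6 do. Clusters 5 and 7 held most epithelial-like cells of control 1 (33.1% and 28.5%) and of scrib 1 (36% and 20%), whereas cluster 0 was the largest in each of the other 6 libraries (15.5% to 19.3%). In 2 epithelial-like clusters the median UMI count lay under 15000 (12681.5 and 11804), with ribosomal RNA precursors among their leading genes. Their share of epithelial-like cells was 19.6% and 22.9% in scrib NAct, 25.1% and 23.4% in scrib RasV12, 5.26% in scrib YkiS168A, 4.77% and 4.46% in scrib and 0.7% in control.

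**Figure D1:**
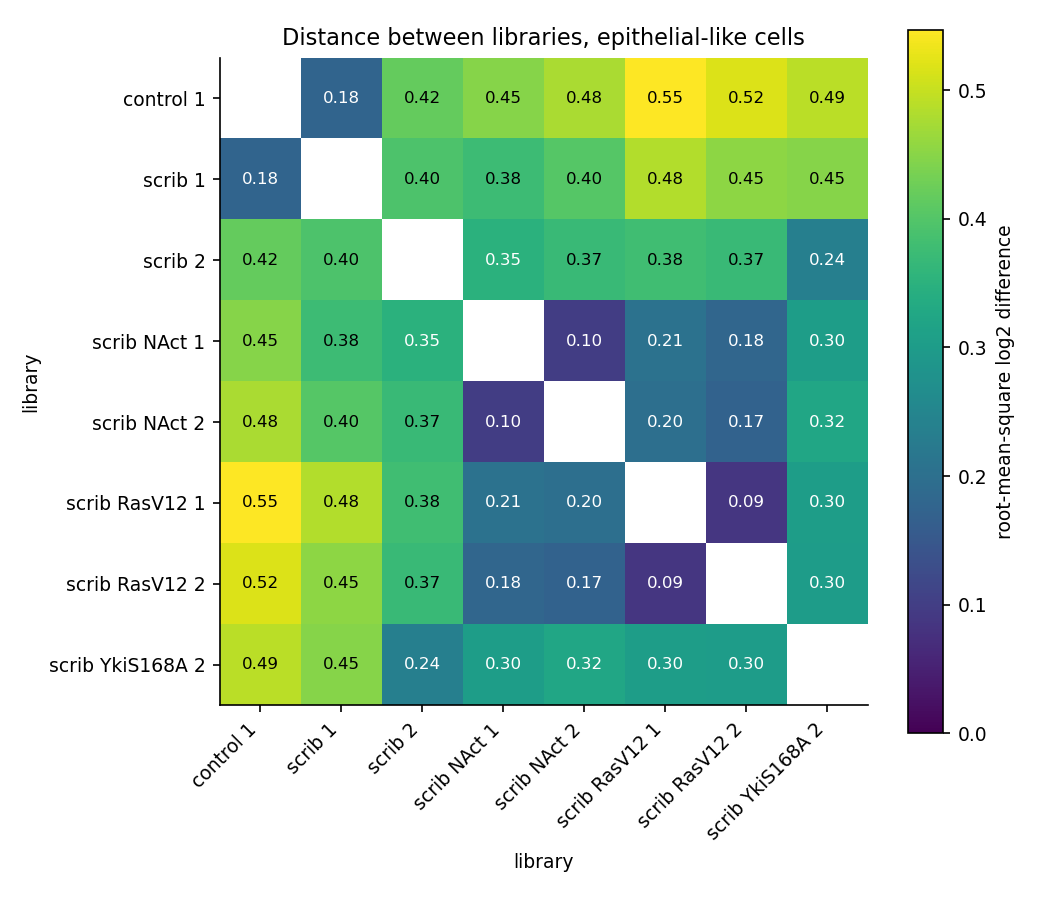
Root-mean-square log2 difference between each pair of the 8 libraries over the epithelial-like cells (both axes list libraries, colour and printed value give the distance). Control 1 and scrib 1 lie 0.176 apart, and scrib 1 lies 0.395 from scrib 2.

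GFP, which marks the clones, was seen in few cells of any genotype. Of epithelial-like cells, 4.13% had a GFP UMI in control (188 of 4555, exact 95% interval 3.57% to 4.75%), 3.78% and 2.63% in scrib, 5.97% and 7.48% in scrib NAct, 6.68% and 5.34% in scrib RasV12 and 5.13% in scrib YkiS168A. These shares lie far below the share of disc area that clones covered, so the cells without a GFP UMI hold undetected clone cells. No disc cell type is known to lack the transgene. In the tracheal-like cluster, 0 of 118 cells had a GFP UMI, which allows a share of up to 2.54%, at a median of 31461 UMIs per cell against 20406 in epithelial-like cells. Cells with a GFP UMI were deeper than the others in every library, with medians of 21796 against 17341 UMIs in control and 24868.5 against 18285 in scrib YkiS168A. Intervals and limits on shares cover counting error only.

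The cluster with the largest share of cells with a GFP UMI, picked for that share, was epithelial-like. Neither GFP nor Gal80 was used for the clustering. In this GFP-rich cluster of 591 cells, the share with a GFP UMI was 54.8% and 30.9% in scrib, 65.2% and 47.6% in scrib NAct, 66.9% and 60.7% in scrib RasV12 and 46% in scrib YkiS168A. Of the other epithelial-like cells in those libraries it was 2.18% to 6.31%. Gal80, carried by cells outside the clones, went the other way, at 2.17% to 5.95% of cells in the cluster and 6.53% to 14.3% outside it in the 6 libraries whose files list it. The shares in the cluster rest on only 1 to 8 cells with a Gal80 UMI. Exact 95% intervals lay apart in scrib RasV12 library 1 (0.825% to 7.52% against 13.1% to 15.5%) and in scrib YkiS168A (2.17% to 9.56% against 11.5% to 13.2%). They overlapped in the others of these libraries. The cluster held 16.5% to 37.4% of the GFP cells of each scrib-mutant library and 0 of the 188 GFP cells of the control library, which allows a share of up to 1.6%.

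**Figure D2:**
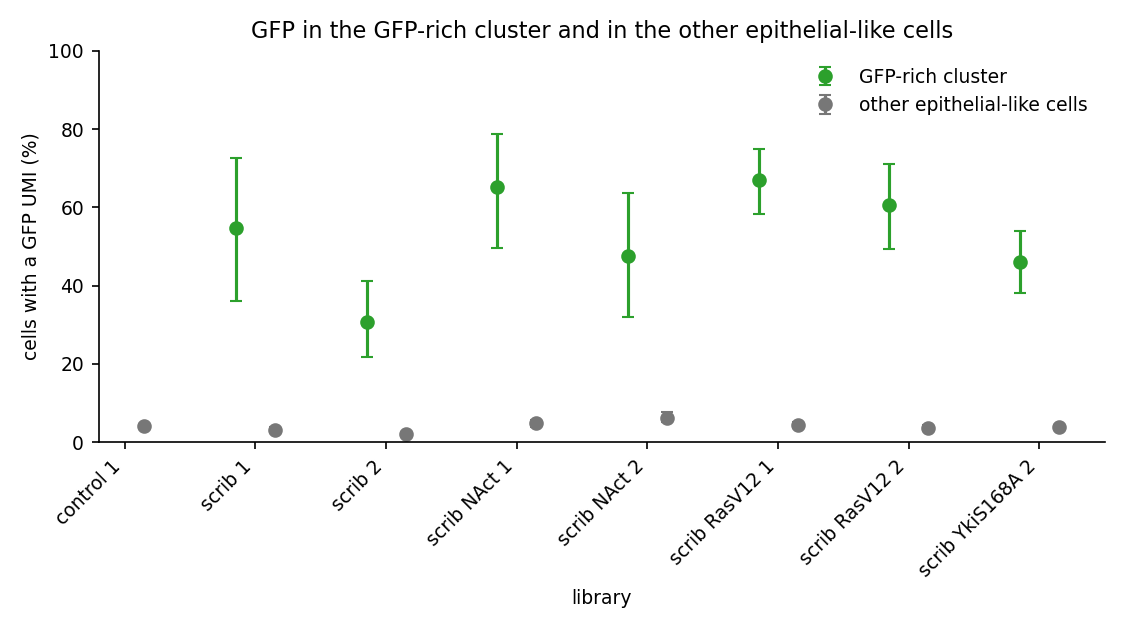
Share of cells with a GFP UMI (percent, y axis) in the GFP-rich cluster and in the other epithelial-like cells of each library (x axis), with exact 95% intervals. The cluster's shares run from 30.9% to 66.9%, the others from 2.18% to 6.31%, and the control library has no cell in the cluster.

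The driver genes were measured next, although a tag near the 3′ end can lie outside the altered part of a gene and then checks no label. Notch (N) rose in scrib NAct clone cells by log2 0.38 ± 0.03 (SE, adjusted p = 1.4e-06, n = 2 libraries), with 1009 against 760.8 counts per-million (CPM, UMIs scaled by the depth of each cell) in library 1 and 1010 against 786.7 in library 2. Ras85D rose in scrib RasV12 clone cells by 0.20 ± 0.05 (adjusted p = 0.0132), at 153.3 against 129.8 and 148.9 against 133.3 CPM. The log2 difference of yki in scrib YkiS168A clone cells was -0.06 ± 0.12 (adjusted p = 0.879), at 56.65 against 59.03 CPM. In clone cells scrib itself fell by 0.42 ± 0.10 in scrib NAct (adjusted p = 0.0127). The log2 difference was -0.17 ± 0.10 in scrib, 0.04 ± 0.10 in scrib RasV12, -0.39 ± 0.14 in scrib YkiS168A and -0.34 ± 0.14 in control, none of these 4 past the test. Over all epithelial-like cells, scrib was at 20.56 CPM in control, 26.69 and 25.88 in scrib, 39.86 and 42.33 in scrib NAct, 39.59 and 41.16 in scrib RasV12 and 26.15 in scrib YkiS168A.

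The clone differences of N in the other 4 genotypes lay between -0.10 and -0.02, those of Ras85D between -0.05 and 0.02 and those of yki between -0.19 and 0.08, none past the test. Over all epithelial-like cells, N was at 526.6 CPM in control, 651.1 and 680.5 in scrib, 775.6 and 803.4 in scrib NAct, 797.5 and 839.3 in scrib RasV12 and 713.7 in scrib YkiS168A. Ras85D was at 201.6 CPM in control, 185 and 140.6 in scrib, 141.1 and 135.2 in scrib NAct, 131.4 and 134.1 in scrib RasV12 and 138.9 in scrib YkiS168A. In the same order yki was at 92.42, 85.19 and 58.99, 61.58 and 62.2, 51.34 and 55.4, and 58.91 CPM. Against scrib, scrib itself rose by 0.63 ± 0.08 in scrib NAct (adjusted p = 0.0117) and by 0.60 ± 0.08 in scrib RasV12 (adjusted p = 0.00853). N rose by 0.25 ± 0.05 in scrib NAct (adjusted p = 0.0466) and by 0.30 ± 0.05 in scrib RasV12 (adjusted p = 0.021), which carries no Notch transgene. No other driver passed the test in the 4 comparisons between genotypes.

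The first set of comparisons asked how clone cells differ from the other cells of the same discs, within each library. In control clones, which carry no scrib mutation, 2 genes of the wing pouch list rose and 2 of the hinge list fell in the single library. The pouch selector gene vg rose by log2 0.62 ± 0.08 and fj, a kinase graded across the pouch, by 0.51 ± 0.06. The genes bnb (0.70 ± 0.09), Cyp310a1 (0.70 ± 0.12), Lsd-2, a lipid droplet perilipin (0.62 ± 0.07), CrebA (0.47 ± 0.10), tun (0.84 ± 0.17) and COX7A (0.34 ± 0.03) rose as well. The hinge homeobox gene hth fell by 0.51 ± 0.05 and Antp by 0.52 ± 0.09. Further falls were Obp99a (-5.15 ± 0.99), the serine protease gene ea (-1.68 ± 0.20), Phk-3 (-1.20 ± 0.16), Tsp97E (-0.92 ± 0.13), hdly (-0.70 ± 0.14), RnrS (-0.52 ± 0.10) and mab-21 (-0.51 ± 0.09).

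Of 6065 genes tested with limma, 15 rose and 19 fell in control clones. List tests in clone comparisons were added after the data were seen. Of 13 wing pouch genes 2 rose and 0 fell (4 and 0 adjusted over the list alone), with a median log2 difference of 0.20 (camera adjusted p = 0.00746, adjusted p = 0.428 with an estimated correlation). Of 10 hinge genes 0 rose and 2 fell (0 and 3 adjusted over the list alone), with a median of -0.21 (adjusted p = 0.0217, adjusted p = 0.428 with an estimated correlation). Of 10 notum genes 0 rose and 0 fell (0 and 3 adjusted over the list alone), with toe at -0.74 ± 0.21 and a median of -0.46 (adjusted p = 0.00013, adjusted p = 0.428 with an estimated correlation). The JNK and stress response list, with 0 of 17 members past either test, had a median of -0.19 (adjusted p = 0.0126, adjusted p = 0.428 with an estimated correlation) and included ftz-f1 at -0.72 ± 0.22. Of 16 Wnt genes 1 rose and 0 fell (2 and 0 adjusted over the list alone). The median was 0.16 (adjusted p = 0.0217, adjusted p = 0.428 with an estimated correlation). In control clones 5 lists were called, and 8 without scrib NAct library 1 or 2. With comparators matched to the clone cells on cluster and UMIs, 8 genes passed the test instead of 34, and 0 passed with cells thinned to 2000 UMIs.

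In scrib clones, genes of the JNK and stress response list and of the apoptosis list were among the largest rises. Mmp1, a matrix metalloproteinase, rose by log2 1.80 ± 0.15 (adjusted p = 1.9e-06, n = 2 libraries) and Ilp8, a relaxin-like peptide through which disturbed discs delay metamorphosis, by 1.44 ± 0.18. The pro-apoptotic genes hid and rpr rose by 1.59 ± 0.09 and 1.33 ± 0.10, and puc, the JNK phosphatase gene, by 1.26 ± 0.10. Ddc, which encodes dopa decarboxylase, rose by 2.35 ± 0.20, vir-1 by 2.03 ± 0.16, yellow-b by 1.77 ± 0.16, GstD3 by 1.64 ± 0.16 and hui by 1.62 ± 0.20. Falls were led by Cpr12A (-2.29 ± 0.31), svp (-1.29 ± 0.26), the FGF ligand genes bnl (-1.27 ± 0.35) and pyr (-1.08 ± 0.16), Skeletor (-1.26 ± 0.16), ImpE2 (-1.19 ± 0.19), Rif1 (-1.10 ± 0.19) and l(2)34Fc (-1.01 ± 0.22). Cpr12A was a leading gene of cluster 10, svp and bnl of cluster 9, ImpE2 of clusters 7 and 13 and l(2)34Fc of cluster 1. These falls may therefore follow from the clusters in which clone cells lay. With comparators matched on cluster and UMIs, 163 values of named genes over all clone comparisons stayed past the test. Another 48 fell short of it and 1 changed sign.

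Of the 17 JNK and stress response genes 10 rose and 0 fell in scrib clones (11 and 0 adjusted over the list alone), with a median of 0.66 (camera adjusted p = 9.7e-10, adjusted p = 0.182 with an estimated correlation). Of 12 apoptosis genes 4 rose and 0 fell (4 and 0 adjusted over the list alone; adjusted p = 0.0001, adjusted p = 0.182 with an estimated correlation), among them the TNF receptor genes grnd (0.67 ± 0.07) and wgn (0.51 ± 0.11). Of 40 cell cycle genes 21 fell and 1 rose (27 and 2 adjusted over the list alone), with a median of -0.22 (adjusted p = 3.9e-07, adjusted p = 0.182 with an estimated correlation). The replication genes RnrS (-0.52) and PCNA (-0.30) had also fallen past the test in control clones. In scrib clones the falls included RnrS (-0.83 ± 0.07), CycE (-0.76 ± 0.12), Mcm3 (-0.65 ± 0.07) and PCNA (-0.62 ± 0.03). Of 59 respiratory chain genes 32 fell and 2 rose (40 and 2 adjusted over the list alone), with ATPsynD at -0.24 ± 0.03 and COX7C at -0.23 ± 0.03 (median -0.14, adjusted p = 7.9e-05, adjusted p = 0.227 with an estimated correlation).

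Of 15 glycolysis genes 10 fell and 1 rose in scrib clones (11 and 1 adjusted over the list alone). The median was -0.22 (adjusted p = 0.00858, adjusted p = 0.321 with an estimated correlation). The gene that rose was ImpL3, which encodes lactate dehydrogenase (0.57 ± 0.15), and the falls included fbp, a gluconeogenic enzyme gene (-0.49 ± 0.09), and Tpi (-0.39 ± 0.05). Ribosomal protein genes rose slightly, 51 of 82 with 3 falling (63 and 3 adjusted over the list alone), for example RpL5 by 0.13 ± 0.02. The median was 0.05 (adjusted p = 2.7e-07, adjusted p = 0.282 with an estimated correlation). Of 29 actomyosin and cytoskeleton genes 11 rose and 0 fell (14 and 1 adjusted over the list alone), including ena (0.56 ± 0.11) and sqh, the myosin regulatory light chain gene (0.46 ± 0.04). The median was 0.06 (adjusted p = 4.8e-06, adjusted p = 0.227 with an estimated correlation). Of 10 notum genes 6 fell and 0 rose (7 and 0 adjusted over the list alone), with pnr at -0.88 ± 0.22 and tsh at -0.77 ± 0.09 (median -0.49, adjusted p = 0.0303, adjusted p = 0.261 with an estimated correlation). In control clones, which carry no scrib mutation, the notum median was -0.46, so a lower notum list was not particular to scrib clones. The Yorkie target list, called as higher (adjusted p = 0.0382, adjusted p = 0.261 with an estimated correlation), differed in sign between its median (-0.01) and mean (0.08), with 6 rising and 2 falling of 23 (6 and 3 adjusted over the list alone).

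In all, 332 genes rose and 604 fell in scrib clones, and 12 of 26 lists were called (8 without scrib library 2). The count was 428 instead of 936 without scrib library 1, 470 without scrib library 2 and 495 without the GFP-rich cluster. Against cells with a Gal80 UMI it was 405 in the 6 libraries whose files list Gal80, which leave out scrib library 1, and 428 in those 6 against all cells without a GFP UMI. The GFP-rich cluster was formed on expression, and its leading genes include Ilp8, vir-1, Mmp1, hid and Ddc. Leaving it out, here and below, removes cells high in these genes, so a smaller rise follows partly from that choice. Without the GFP-rich cluster the JNK and stress response list had a median of 0.29 with 6 rising and actomyosin genes one of 0.03 with 5 rising. Glycolysis genes then had a median of -0.14 with 3 falling and respiratory chain genes one of -0.11 with 17 falling, while 15 cell cycle genes fell (median -0.22). The Yorkie target list was not called there (adjusted p = 0.148, 2 rising and 3 falling). The labels do not say that libraries of a genotype came from separate sets of animals, so p-values here and below measure only the spread between these libraries.

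In scrib NAct clones, Notch target genes rose in addition to stress genes. Genes of the Enhancer of split complex, a main target of Notch signalling, rose by log2 2.19 ± 0.10 for E(spl)m2-BFM (adjusted p = 2.1e-08, n = 2 libraries), 2.04 ± 0.17 for E(spl)m8-HLH and 2.0 ± 0.24 for E(spl)mgamma-HLH. The related repressor gene dpn rose by 1.71 ± 0.09. The Wnt ligand genes Wnt6 and wg rose by 2.06 ± 0.11 and 1.77 ± 0.10, Ilp8 by 2.92 ± 0.18 and GstD3 by 1.81 ± 0.16. The largest falls were ltl (-1.93 ± 0.19), Osi14 (-1.91 ± 0.17), comm (-1.83 ± 0.22), aos, which encodes a secreted EGFR antagonist induced by EGFR itself (-1.83 ± 0.15), and Pvf3, a PDGF- and VEGF-like ligand gene (-1.83 ± 0.25). Further falls in these cells were the sensory organ gene Poxn (-1.69 ± 0.25), GV1 (-1.46 ± 0.18) and trh (-1.42 ± 0.29). As ltl was a leading gene of cluster 7, Osi14 of cluster 0 and Poxn of cluster 15, these falls may also follow from where clone cells lay.

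Of 21 Notch targets 15 rose and 3 fell in scrib NAct clones (15 and 4 adjusted over the list alone). The median was 0.98 (camera adjusted p = 7.5e-10, adjusted p = 0.138 with an estimated correlation). Of 17 JNK and stress response genes 10 rose and 1, Pvf3, fell (10 and 1 adjusted over the list alone), with Mmp1 at 1.42 ± 0.15 and rpr at 1.16 ± 0.10. The median was 0.48 (adjusted p = 3.4e-07, adjusted p = 0.192 with an estimated correlation). Of 26 EGFR, Ras and MAPK targets 8 fell and 2 rose (10 and 3 adjusted over the list alone), with vvl at -1.29 ± 0.08 and cv-2 at -0.88 ± 0.17. The median was -0.20 (adjusted p = 0.00486, adjusted p = 0.192 with an estimated correlation). Of 23 Yorkie targets 9 rose and 1 fell (10 and 1 adjusted over the list alone), including Diap1, an inhibitor of apoptosis (0.61 ± 0.05), and the glypican gene dally (0.59 ± 0.05). The median was 0.10 (adjusted p = 1.5e-05, adjusted p = 0.172 with an estimated correlation). Proneural genes fell in 3 of 7 cases and rose in 0 (5 and 0 adjusted over the list alone), with sc at -0.77 ± 0.15 and sca at -0.71 ± 0.17. The median was -0.68 (adjusted p = 0.0137, adjusted p = 0.305 with an estimated correlation). Of 15 glycolysis genes 11 fell and 0 rose (12 and 1 adjusted over the list alone), among them Pfk (-0.52 ± 0.09) and Ald (-0.42 ± 0.05). The median was -0.30 (adjusted p = 0.00048, adjusted p = 0.307 with an estimated correlation).

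The wing margin and pouch gene vg, which had also risen past the test in control clones, rose by 0.89 ± 0.06 in scrib NAct clones. The Wnt feedback gene Notum fell by 1.0 ± 0.10 in them. Both belong to the Wnt list, of whose 16 members 6 rose and 3 fell (7 and 3 adjusted over the list alone). The median was 0.08 (adjusted p = 0.048, adjusted p = 0.305 with an estimated correlation). In all, 296 genes rose and 414 fell, and 10 of 26 lists were called (6 without scrib NAct library 1). The count was 356 instead of 710 without scrib NAct library 1, 471 without library 2 and 396 without the GFP-rich cluster. Without that cluster the EGFR, Ras and MAPK list had a median of -0.13 with 5 falling (adjusted p = 0.0495), proneural genes one of -0.49 with 1 falling, Yorkie targets one of 0.22 with 9 rising and the Wnt list one of 0.14. Glycolysis genes then fell in 7 cases (median -0.28).

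In scrib RasV12 clones, Ilp8 rose by log2 3.94 ± 0.18 (adjusted p = 4.1e-09, n = 2 libraries), vir-1 by 3.08 ± 0.16 and Mmp1 by 3.01 ± 0.15. Ddc rose by 2.05 ± 0.20, the matrix gene tnc by 1.99 ± 0.20, hid by 1.90 ± 0.09, yellow-b by 1.84 ± 0.16 and the sulfatase gene Sulf1 by 1.83 ± 0.17. The largest falls were Hsp67Ba (-1.50 ± 0.13), the cuticle protein genes Cpr66D (-1.43 ± 0.18) and Lcp65Ag2 (-1.40 ± 0.27), ImpE3 (-1.34 ± 0.21), ea (-1.33 ± 0.14), the EGFR ligand gene vn (-1.08 ± 0.14), plum (-1.08 ± 0.10) and hdly (-1.06 ± 0.10). Of these, Lcp65Ag2 was a leading gene of cluster 6 and vn of cluster 9, so the position of clone cells may matter here too.

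Of 17 JNK and stress response genes 11 rose and 0 fell in scrib RasV12 clones (11 and 0 adjusted over the list alone), including kay, the fly Fos gene (1.62 ± 0.13), and puc (1.57 ± 0.10). The median was 0.80 (camera adjusted p = 7.3e-09, adjusted p = 0.186 with an estimated correlation). Of 29 actomyosin and cytoskeleton genes 19 rose and 1 fell (20 and 1 adjusted over the list alone), with betaTub60D at 1.0 ± 0.17, ena at 0.86 ± 0.11 and the myosin genes zip and sqh at 0.65 ± 0.05 and 0.63 ± 0.04. The median was 0.26 (adjusted p = 3.9e-10, adjusted p = 0.186 with an estimated correlation). Of 40 cell cycle genes 23 fell and 1 rose (27 and 3 adjusted over the list alone), with RnrS at -0.96 ± 0.07, Mcm2 at -0.81 ± 0.08 and Mcm7 at -0.77 ± 0.06. The median was -0.22 (adjusted p = 2.8e-08, adjusted p = 0.186 with an estimated correlation). Of 17 insulin and amino-acid signalling genes 7 rose and 1 fell (8 and 1 adjusted over the list alone), with the insulin-binding protein gene ImpL2 at 1.48 ± 0.11, Thor, which encodes the translation inhibitor 4E-BP, at 1.34 ± 0.33 and the amino acid transporter gene path at 0.93 ± 0.10. The median was 0.15 (adjusted p = 0.00048, adjusted p = 0.234 with an estimated correlation).

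Of 21 adherens junction and apical polarity genes 8 rose and 1 fell in scrib RasV12 clones (9 and 1 adjusted over the list alone), including Vinc (0.69 ± 0.14), pyd (0.68 ± 0.07) and shg, the E-cadherin gene (0.33 ± 0.06). The median was 0.08 (adjusted p = 0.0117, adjusted p = 0.234 with an estimated correlation). Of 26 EGFR, Ras and MAPK targets 7 rose and 7 fell, and the list was not called (adjusted p = 0.724). In all, 459 genes rose and 464 fell, and 8 of 26 lists were called (4 without scrib RasV12 library 2). The count was 451 instead of 923 without scrib RasV12 library 1, 426 without library 2 and 540 without the GFP-rich cluster. Without that cluster the JNK and stress response list had a median of 0.55 with 8 rising, actomyosin genes one of 0.15 with 13 rising and cell cycle genes one of -0.12 with 13 falling.

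In scrib YkiS168A clones, measured in a single library, Ilp8 rose by log2 4.27 ± 0.25 (adjusted p = 3.9e-07) and ImpL3, the lactate dehydrogenase gene, by 3.59 ± 0.22. The gene w, an eye pigment transporter gene and a common marker on transgenes, rose by 3.11 ± 0.32, fs(1)K10 by 2.75 ± 0.35, vir-1 by 2.49 ± 0.22, hui by 2.18 ± 0.29, GstD3 by 2.12 ± 0.22 and Mmp1 by 2.09 ± 0.21. The largest falls were Hsp67Ba (-2.0 ± 0.19), Cpr66D (-1.70 ± 0.26), ea (-1.68 ± 0.20), plum (-1.66 ± 0.15), hbs (-1.49 ± 0.28), Cpr49Ah (-1.31 ± 0.26), a leading gene of clusters 0 and 15, Skeletor (-1.31 ± 0.22) and obst-A (-1.27 ± 0.22).

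Of 23 Yorkie targets 10 rose and 0 fell in scrib YkiS168A clones (12 and 2 adjusted over the list alone), with the Hippo pathway gene kibra at 1.55 ± 0.17, Wnt6 at 0.93 ± 0.15 and dlp at 0.67 ± 0.12. The median was 0.26 (camera adjusted p = 1.1e-05, adjusted p = 0.226 with an estimated correlation). Of 17 JNK and stress response genes 9 rose and 0 fell (9 and 0 adjusted over the list alone), including kay (0.94 ± 0.18) and puc (0.89 ± 0.14). The median was 0.62 (adjusted p = 4.1e-06, adjusted p = 0.226 with an estimated correlation). Of 21 Notch targets 7 fell and 2 rose (9 and 2 adjusted over the list alone): E(spl)m4-BFM was at -1.08 ± 0.24 and E(spl)mdelta-HLH at -0.94 ± 0.24, while wg rose by 1.16 ± 0.15. The median was -0.29 (adjusted p = 0.0304, adjusted p = 0.247 with an estimated correlation). Of 59 respiratory chain genes 6 rose and 0 fell (6 and 0 adjusted over the list alone), including the cytochrome c gene Cyt-c-p (0.67 ± 0.06). The median was 0.08 (adjusted p = 0.00011, adjusted p = 0.226 with an estimated correlation). Of 15 glycolysis genes 4 fell and 1, ImpL3, rose (5 and 1 adjusted over the list alone), so that the list's median (-0.21) and its test (lower, adjusted p = 0.0156, adjusted p = 0.34 with an estimated correlation) differed in sign from its mean (0.02).

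In all, 216 genes rose, 190 fell and 15 of 26 lists were called in scrib YkiS168A clones, and this single library was assumed to vary as much as the pairs did. The count was 253 instead of 406 with at least 2 GFP UMIs required, 233 with comparators matched on cluster and UMIs and 225 without the GFP-rich cluster. Without that cluster 4 JNK and stress response genes rose (median 0.48), as did 8 Yorkie targets (0.25) and 3 respiratory chain genes (0.08), while 4 Notch targets (-0.25) and 3 glycolysis genes (-0.14, adjusted p = 0.049) fell. Thinning every cell to 2000 UMIs left 47 genes past the test in scrib clones, 44 in scrib NAct, 54 in scrib RasV12 and 0 in scrib YkiS168A.

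**Figure D3:**
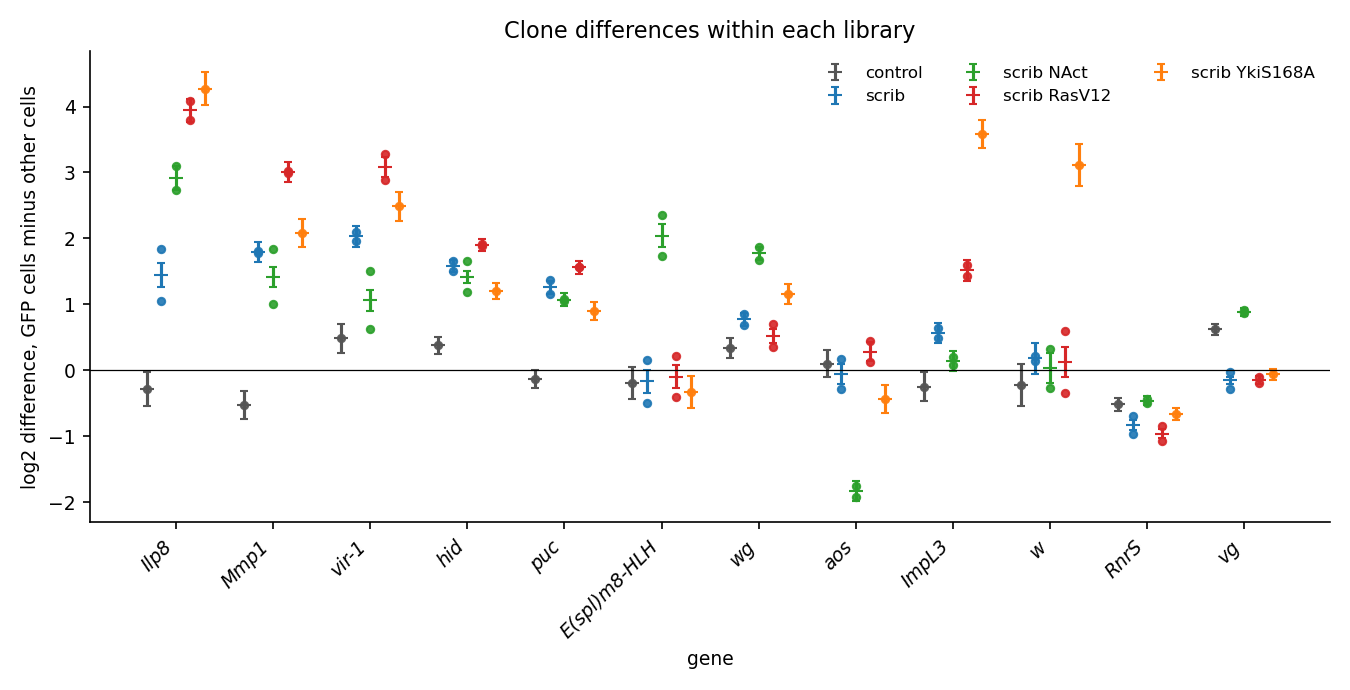
Log2 difference between GFP cells and other cells (y axis) for 12 genes (x axis); points are libraries, ticks with bars are the fitted value ± SE for each of the 5 genotypes. Among the 4 scrib genotypes Ilp8 runs from 1.44 in scrib to 4.27 in scrib YkiS168A, and it lies at -0.28 in control. E(spl)m8-HLH reaches 2.04 in scrib NAct, and ImpL3 reaches 3.59 in scrib YkiS168A.

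**Figure D4:**
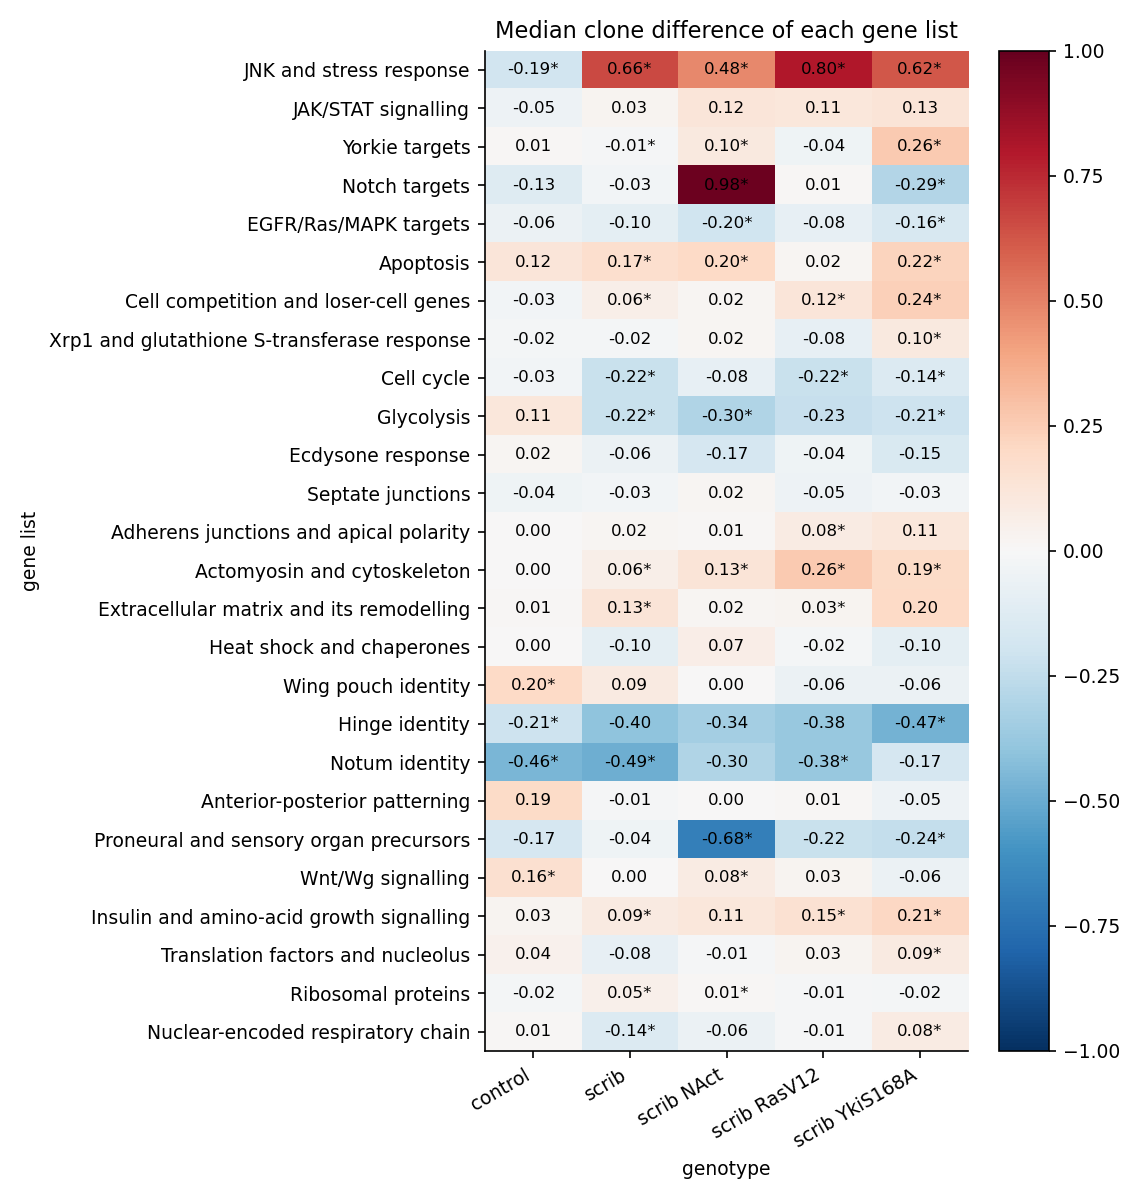
Median log2 difference between GFP cells and other cells for the 26 tested gene lists (y axis) in each genotype (x axis); a star marks lists with an adjusted p under 0.05 by camera with a preset correlation of 0.01, none of which passed with an estimated correlation. The JNK and stress response list has medians of 0.66, 0.48, 0.80 and 0.62 in the 4 scrib genotypes and -0.19 in control, and Notch targets reach 0.98 in scrib NAct.

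The second set of comparisons asked how the epithelium as a whole, clone and non-clone cells together, differed between genotypes. For scrib against control, 1 gene passed the test and 467 lay at an unadjusted p under 0.05 with limma. The gene, CG9186, was named after its value was seen: it rose by log2 1.70 ± 0.09 (adjusted p = 0.0211), from 23.76 CPM in control to 83.60 and 75.48 CPM in scrib. The genes next nearest the threshold were Mgstl, a microsomal glutathione transferase gene (1.07 ± 0.08, adjusted p = 0.0537), Ctr9 (1.59 ± 0.15), Ude (0.95 ± 0.11) and Hsp70Ab (1.05 ± 0.15) among higher values. Among lower values they were Ance (-0.80 ± 0.07), escl (-1.33 ± 0.22), E(spl)mbeta-HLH (-0.35 ± 0.06) and klu (-0.52 ± 0.09).

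Of 26 lists 7 were called. As a set, the 17 JNK and stress response genes were higher in scrib than in control (median 0.41, camera adjusted p = 1.4e-15, adjusted p = 0.157 with an estimated correlation). Of them 0 rose and 0 fell over all genes, but 11 rose and 0 fell adjusted over the list alone, with Ilp8 at 1.36 ± 0.20 and chinmo at 1.06 ± 0.27. Of 14 extracellular matrix genes 0 rose and 0 fell (0 and 0 adjusted over the list alone), with trol at 0.79 ± 0.21. The median was 0.12 (adjusted p = 0.00014, adjusted p = 0.616 with an estimated correlation), and 0.05 without the low-UMI clusters. The 82 ribosomal protein genes, 0 of them past either test, had a median of 0.10 (adjusted p = 3.8e-19, adjusted p = 0.652 with an estimated correlation), which became -0.02 with the batch term. For the heat shock list the median (-0.01) and the mean (0.10) differed in sign while the test called it higher (adjusted p = 0.00037, adjusted p = 0.298 with an estimated correlation). Of its 19 members 0 rose and 0 fell (2 and 0 adjusted over the list alone). Neither the heat shock list (adjusted p = 0.263) nor the ribosomal protein list (adjusted p = 0.461) was called after quantile normalization, nor was either with the batch term (adjusted p = 0.161 for both). With a batch term for whether the file lists Gal80, the comparison becomes scrib library 1 against control 1, with Mgstl at 1.01. Its error then comes only from the scrib NAct and scrib RasV12 pairs and holds no spread between scrib or control libraries. Without scrib library 1 the count was 4205 (441 up and 3764 down), without scrib library 2 it was 566 (320 up and 246 down), and without any of the 4 scrib NAct or scrib RasV12 libraries in turn it was 0.

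In scrib NAct discs against scrib discs, Ilp8 rose by log2 2.15 ± 0.17 (adjusted p = 0.01, n = 2 against 2 libraries) and Hsp70Ab by 1.87 ± 0.12. Further rises were those of the fatty acid synthase gene FASN1 by 1.25 ± 0.15, E(spl)m4-BFM by 1.23 ± 0.22, the nucleoporin gene Nup153 by 1.19 ± 0.09 and the mechanosensitive channel gene Piezo by 1.17 ± 0.17. The genes pigs (1.25 ± 0.08) and osp (1.14 ± 0.10), which also rose, were among the leading genes of a low-UMI cluster, and without the low-UMI clusters they were at 1.02 and 0.84. The largest falls were GstE1 (-1.66 ± 0.10), the arginine kinase gene Argk (-1.49 ± 0.27), Cpr51A (-1.27 ± 0.28), the juvenile hormone epoxide hydrolase gene Jheh1 (-1.03 ± 0.14), ltl (-1.0 ± 0.21), GstT4 (-0.99 ± 0.19), obst-B (-0.98 ± 0.15) and spz6 (-0.82 ± 0.15). Argk was a leading gene of cluster 5 and ltl of cluster 7, which hold mostly cells of control 1 and scrib 1. With the batch term, which leaves scrib library 2 as the reference, Argk was at -1.04 and ltl at -0.74.

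Of 21 Notch targets 8 rose and 0 fell in scrib NAct against scrib (12 and 0 adjusted over the list alone), among them E(spl)mgamma-HLH (1.14 ± 0.13), E(spl)m8-HLH (1.08 ± 0.11) and the ligand gene Dl (0.97 ± 0.21). The median was 0.34 (camera adjusted p = 4.9e-05, adjusted p = 0.385 with an estimated correlation). Of 23 Yorkie targets 11 rose and 0 fell (14 and 1 adjusted over the list alone), including crb (0.99 ± 0.08), ex (0.90 ± 0.09) and ft (0.85 ± 0.09), which are also Hippo pathway regulators. The median was 0.42 (adjusted p = 1.7e-06, adjusted p = 0.385 with an estimated correlation). Of 14 extracellular matrix genes 8 rose and 0 fell (11 and 0 adjusted over the list alone), including wb (1.12 ± 0.20), a leading gene of a low-UMI cluster, and Mmp1 (0.84 ± 0.14). The median was 0.49 (adjusted p = 1e-05, adjusted p = 0.385 with an estimated correlation). Of 17 JNK and stress response genes 8 rose and 0 fell (9 and 1 adjusted over the list alone). The median was 0.29 (adjusted p = 0.00104, adjusted p = 0.385 with an estimated correlation). Of 13 anterior-posterior patterning genes 7 rose and 0 fell (8 and 1 adjusted over the list alone), with brk at 1.04 ± 0.08. The median was 0.47 (adjusted p = 0.00046, adjusted p = 0.487 with an estimated correlation). Glycolysis genes were lower, with 2 falling and 1, the HIF gene sima, rising (5 and 1 adjusted over the list alone). The median was -0.33 (adjusted p = 0.00263, adjusted p = 0.59 with an estimated correlation), and -0.16 with 9 falling and 3 rising with the batch term. The ecdysone list differed in sign between its median (0.35) and mean (-0.03), with 3 of 13 rising and 0 falling (6 and 2 adjusted over the list alone). The test called it higher (adjusted p = 0.0268, adjusted p = 0.506 with an estimated correlation), but not without the low-UMI clusters (adjusted p = 0.235) or with the batch term (adjusted p = 0.173). Without the low-UMI clusters fewer members rose: 1 JNK and stress response gene (median 0.09), 1 extracellular matrix gene (0.31), 2 anterior-posterior genes (0.31), 5 Yorkie targets (0.31) and 5 Notch targets (0.22). Glycolysis genes then fell in 0 cases (median -0.25), and these 6 lists were still called.

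In all, 496 genes rose, 107 fell and 15 of 26 lists were called in scrib NAct against scrib, and 2316 rose and 730 fell with the batch term. The split was 694 up and 691 down with libraries centred on their median and 750 and 839 after quantile normalization. Without the low-UMI clusters the count was 100. Leaving out scrib library 1 gave 3042 genes (2316 up and 726 down) and leaving out scrib library 2 gave 4166 (1127 up and 3039 down), so the balance of direction depended on the scrib library kept. Leaving out any of the 4 scrib NAct or scrib RasV12 libraries gave 0, as did a fit of the scrib and scrib NAct libraries alone.

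In scrib RasV12 discs against scrib discs, the largest rises were Hsp70Ab (log2 1.75 ± 0.12, adjusted p = 0.00385, n = 2 against 2 libraries), pigs (1.69 ± 0.08) and the Dpp target gene salm (1.62 ± 0.14). Next came Ilp8 (1.60 ± 0.17), osp (1.51 ± 0.10), chinmo (1.41 ± 0.22), ftz-f1 (1.38 ± 0.15) and robo2 (1.35 ± 0.15). The largest falls were the ecdysone-inducible genes ImpE2 (-4.53 ± 0.76) and ImpE3 (-1.56 ± 0.31), the cuticle protein genes Cpr51A (-2.31 ± 0.28) and Cpr12A (-1.45 ± 0.18), Argk (-1.79 ± 0.27), GV1 (-1.73 ± 0.39), GstE1 (-1.27 ± 0.10) and Inos (-1.10 ± 0.14). ImpE2 was a leading gene of cluster 7 and Argk of cluster 5, which hold mostly cells of control 1 and scrib 1, and with the batch term they were at -3.27 and -1.34. As leading genes of a low-UMI cluster, pigs and osp were at 1.44 and 1.17 without the low-UMI clusters.

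Of 26 EGFR, Ras and MAPK targets 11 rose and 0 fell in scrib RasV12 against scrib (11 and 1 adjusted over the list alone), including Egfr (1.03 ± 0.09), the feedback inhibitor gene sty (0.83 ± 0.13) and vn (0.70 ± 0.08). The median was 0.30 (camera adjusted p = 1.8e-06, adjusted p = 0.506 with an estimated correlation). This rise was not particular to scrib RasV12. With libraries centred on their median, the list was also called higher in scrib NAct against scrib (median 0.18, camera adjusted p = 0.00206). There 7 members rose and 3 fell, against 14 and 1 in scrib RasV12 (median 0.33). Of 17 JNK and stress response genes 11 rose and 0 fell (11 and 0 adjusted over the list alone), including Mmp1 (1.30 ± 0.14). The median was 0.59 (adjusted p = 1.7e-06, adjusted p = 0.418 with an estimated correlation). Of 23 Yorkie targets 12 rose and 1 fell (13 and 2 adjusted over the list alone), with crb at 1.13 ± 0.08 and kibra at 1.08 ± 0.09. The median was 0.58 (adjusted p = 3.2e-06, adjusted p = 0.418 with an estimated correlation). Of 13 wing pouch genes 6 rose and 1 fell (7 and 1 adjusted over the list alone). The median was 0.58 (adjusted p = 9.8e-05, adjusted p = 0.418 with an estimated correlation). Of 17 insulin and amino-acid signalling genes 8 rose and 0 fell (8 and 0 adjusted over the list alone), with InR, the insulin receptor gene, at 0.83 ± 0.06. The median was 0.44 (adjusted p = 3.2e-05, adjusted p = 0.418 with an estimated correlation). Of 13 ecdysone genes 7 rose and 2 fell (8 and 3 adjusted over the list alone), with Kr-h1 at 1.29 ± 0.20. Their median (0.32) and the test (higher, adjusted p = 0.00863, adjusted p = 0.506 with an estimated correlation) differed in sign from the mean (-0.08), and the list was not called with the batch term (adjusted p = 0.0512). Of 15 glycolysis genes 6 fell and 2 rose (11 and 2 adjusted over the list alone), with Tpi at -0.55 ± 0.11 and Hex-A at 0.58 ± 0.13. The median was -0.41 (adjusted p = 0.0295, adjusted p = 0.785 with an estimated correlation). Without the low-UMI clusters 8 EGFR, Ras and MAPK targets rose (median 0.36), as did 8 JNK and stress response genes (0.46), 11 Yorkie targets (0.37), 4 wing pouch genes (0.32), 4 insulin and amino-acid signalling genes (0.50) and 3 ecdysone genes (0.15). Glycolysis genes then fell in 1 case (median -0.34), and these 7 lists were still called. With the batch term 21 EGFR, Ras and MAPK targets rose (median 0.48) and 11 glycolysis genes fell (-0.26).

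In all, 668 genes rose, 385 fell and 15 of 26 lists were called in scrib RasV12 against scrib, and 1821 rose and 1397 fell with the batch term. The split was 967 up and 1163 down with libraries centred on their median and 1024 and 1347 after quantile normalization. Without the low-UMI clusters the count was 442, and a fit of the scrib and scrib RasV12 libraries alone gave 296. Leaving out scrib library 1 gave 3224 genes (1823 up and 1401 down), and leaving out scrib library 2 gave 4682 (1106 up and 3576 down), so here too the balance turned with the scrib library kept. Leaving out scrib NAct library 1 or 2 gave 278 and 276, and leaving out either scrib RasV12 library gave 0.

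In the single scrib YkiS168A library against scrib, 8 genes rose and 3 fell. The named rises were the growth factor gene Idgf6 (log2 1.11 ± 0.09, adjusted p = 0.0409), pigs (1.06 ± 0.09), the aldehyde dehydrogenase gene Aldh (1.01 ± 0.08), hdc (0.76 ± 0.07) and the tetraspanin gene Tsp42Ea (0.68 ± 0.06). The falls were the glutathione transferase genes GstE1 (-1.47 ± 0.12) and GstE5 (-1.42 ± 0.11) and the cuticle protein gene Cpr49Ah (-1.24 ± 0.10). With the replicate block or without the variance trend, no gene passed the test. Argk, a leading gene of cluster 5, was at -3.03 ± 0.33 and missed the threshold (adjusted p = 0.06).

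The JNK and stress response list was higher in scrib YkiS168A than in scrib (median 0.37, camera adjusted p = 3.3e-08, adjusted p = 0.399 with an estimated correlation). Of its 17 members 0 rose and 0 fell (8 and 0 adjusted over the list alone). The Yorkie target list, which shares Ilp8 with the JNK and stress response list, was also called higher (adjusted p = 4.4e-05, adjusted p = 0.54 with an estimated correlation). Its median was 0.02, against -0.108 for all genes, so the call is relative to the other genes. Of 23 tested 0 rose and 0 fell (7 and 0 adjusted over the list alone, and 11 and 0 over all genes with the batch term, where the median was 0.15), with Ilp8 at 1.49 ± 0.20 and kibra at 0.61 ± 0.11. Of 26 lists 9 were called. Heat shock genes were lower (median -0.25, adjusted p = 0.014, adjusted p = 0.54 with an estimated correlation), with 0 of 19 rising and 0 falling (0 and 2 adjusted over the list alone) and Hsp67Ba at -1.74 ± 0.22. The 82 ribosomal protein genes, 0 of them past either test, had a median of 0.12 (adjusted p = 4.5e-14, adjusted p = 0.715 with an estimated correlation), and after quantile normalization the list was not called (median 0.03, adjusted p = 0.132), nor was it with the batch term (adjusted p = 0.773). With the batch term 721 genes rose and 490 fell. The split was 51 up and 37 down with libraries centred on their median and 58 and 36 after quantile normalization. Leaving out scrib library 1 gave 1224 genes (732 up and 492 down) and leaving out scrib library 2 gave 4067 (573 up and 3494 down), again with the opposite balance. Leaving out any of the 4 scrib NAct or scrib RasV12 libraries gave 0, and the count was 5 without the low-UMI clusters.

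The median of all 6065 genes lay at log2 -0.128 for scrib against control, -0.037 for scrib NAct, -0.117 for scrib RasV12 and -0.108 for scrib YkiS168A against scrib, so CPM values carry that shift. Centred on their medians, scrib against control had list medians of 0.26 for extracellular matrix and 0.25 for ribosomal protein genes, and scrib YkiS168A against scrib had -0.15 for heat shock genes, 0.12 for Yorkie targets and 0.22 for ribosomal protein genes. No gene named in these 4 comparisons changed sign under either scaling, and of the lists called only the heat shock median of scrib against control did (0.14 when centred). The low-UMI clusters and the split by Gal80 row moved with genotype: scrib NAct and scrib RasV12 had the most low-UMI cells, and control 1 lay with scrib 1. The share of cells with a roX1 UMI, read here for the mix of male and female larvae, also differed between genotypes. It was 31% and 32.7% in scrib RasV12, 49.3% and 54.1% in scrib NAct and 38.4% and 48.4% in scrib. Its effect on these comparisons was not tested. With the batch term, each comparison with scrib rests on scrib library 2 and the comparison with control on scrib library 1. The difference between the scrib libraries then leaves the error, whose 2 residual degrees of freedom come from the scrib NAct and scrib RasV12 pairs. The larger counts with the batch term therefore rest on no spread between scrib or control libraries.

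**Figure D5:**
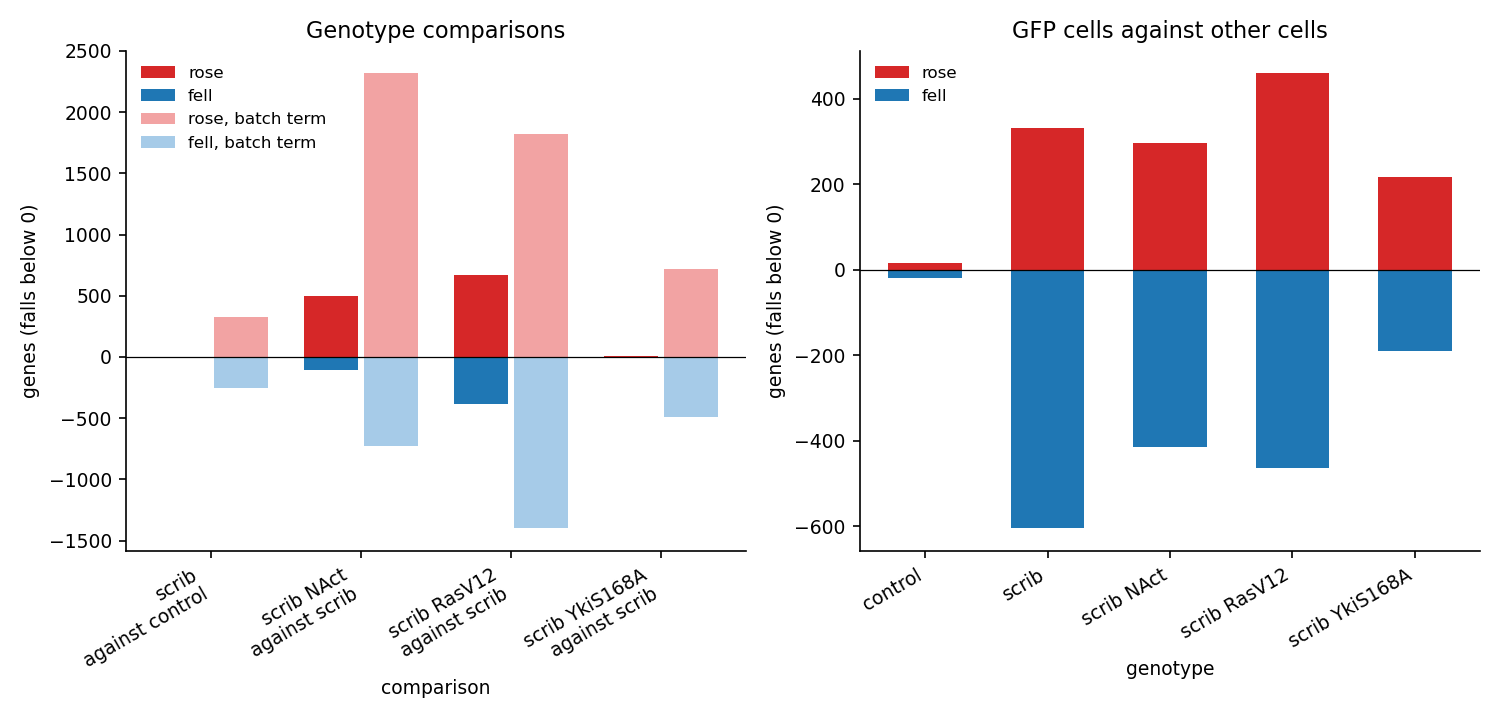
Number of genes that rose (above 0) and fell (below 0) in each genotype comparison, without and with the batch term (left), and in GFP cells against other cells in each genotype (right); y axes count genes of 6065 tested. Counts with the batch term reach 2316 rises for scrib NAct, and clone counts are 15 rises and 19 falls in control, 332 and 604 in scrib and 459 and 464 in scrib RasV12.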

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

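All tests in this part were chosen after the result was seen. The difference between clone cells and other cells was compared between genotypes with limma, within the clone fit, because clone differences had been seen to differ. At least 2 GFP UMIs were seen in 74 of 188 clone cells of control. In scrib it was 43 of 103 and 67 of 157, in scrib NAct 75 of 143 and 57 of 111. It was 160 of 238 and 110 of 160 in scrib RasV12 and 187 of 294 in scrib YkiS168A. How surely 1 GFP UMI marks a clone cell may thus differ between genotypes. A gap between clone differences can then follow from GFP level, which was not tested apart.

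Between scrib and control, the clone difference differed for 184 genes (107 higher and 77 lower in scrib), or 103 without scrib library 1 and 110 without scrib library 2. It was higher in scrib for yellow-b (log2 2.65 ± 0.27), Mmp1 (2.32 ± 0.26), hui (2.04 ± 0.35) and Ddc (1.93 ± 0.34), and lower for Cpr12A (-3.70 ± 0.54), ImpE2 (-1.39 ± 0.33), LpR2 (-1.09 ± 0.21) and plum (-0.88 ± 0.18). Of 17 JNK and stress response genes 8 were higher and 0 lower (9 and 0 adjusted over the list alone). The median was 0.66 (adjusted p = 0.226 with an estimated correlation). Of 15 glycolysis genes 0 were higher and 7 lower (1 and 10 adjusted over the list alone), with a median of -0.38 (adjusted p = 0.33 with an estimated correlation). Cell cycle genes had a median of -0.27 (0 and 5 of 40, 0 and 16 adjusted over the list alone, adjusted p = 0.226 with an estimated correlation). Respiratory chain genes had a median of -0.15 (0 and 8 of 59, 0 and 16 adjusted over the list alone, adjusted p = 0.274 with an estimated correlation). The Xrp1 list was called higher although its median was -0.04 and its mean 0.11 (adjusted p = 0.33 with an estimated correlation).

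Between scrib NAct and scrib it differed for 95 genes (55 higher, 40 lower). It was higher in scrib NAct for Cpr12A (log2 3.31 ± 0.44), E(spl)m8-HLH (2.21 ± 0.24), E(spl)mgamma-HLH (2.08 ± 0.34) and E(spl)m2-BFM (1.90 ± 0.14), and lower for ltl (-3.29 ± 0.27), trh (-2.20 ± 0.41), Osi14 (-2.12 ± 0.24) and aos (-1.77 ± 0.21). Of 21 Notch targets 14 were higher and 2 lower (15 and 3 adjusted over the list alone). The median was 0.91 (adjusted p = 0.137 with an estimated correlation). Of 40 cell cycle genes 6 were higher and 0 lower (19 and 0 adjusted over the list alone), with a median of 0.18 (adjusted p = 0.137 with an estimated correlation). Yorkie targets had a median of 0.17 (4 and 0 of 23, 7 and 0 adjusted over the list alone, adjusted p = 0.174 with an estimated correlation). Proneural genes had a median of -0.43 (0 and 1 of 7, 0 and 1 adjusted over the list alone, adjusted p = 0.372 with an estimated correlation).

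Between scrib RasV12 and scrib it differed for 170 genes (101 higher, 69 lower), or 42 and 85 without scrib library 1 or 2 and 67 and 29 without scrib RasV12 library 1 or 2. It was higher in scrib RasV12 for Cpr12A (log2 2.64 ± 0.44), Ilp8 (2.50 ± 0.25), svp (1.58 ± 0.37) and ImpE1 (1.56 ± 0.25), and lower for Lcp65Ag2 (-1.57 ± 0.38), ltl (-1.51 ± 0.27), stwl (-1.21 ± 0.26) and GstT4 (-1.07 ± 0.23). Insulin and amino-acid signalling genes were higher for 2 of 17 (4 adjusted over the list alone, median 0.18) and actomyosin genes for 7 of 29 (9 adjusted over the list alone, median 0.17). Respiratory chain genes were higher for 11 of 59 (27 adjusted over the list alone, median 0.13), and ribosomal protein genes lower for 22 of 82 (59 adjusted over the list alone, median -0.06). Each of these 4 lists had an adjusted p of 0.514 with an estimated correlation.

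Between scrib YkiS168A and scrib it differed for 152 genes (90 higher, 62 lower), or 74 without scrib library 1 and 81 without scrib library 2. It was higher in scrib YkiS168A for ImpL3 (log2 3.02 ± 0.26), w (2.93 ± 0.39), Ilp8 (2.82 ± 0.31) and fs(1)K10 (2.59 ± 0.43), and lower for E(spl)m4-BFM (-1.85 ± 0.29), hbs (-1.46 ± 0.35), Hsp67Ba (-1.23 ± 0.23) and drl (-1.03 ± 0.16). Yorkie targets were higher for 3 of 23 (11 adjusted over the list alone, median 0.28) and respiratory chain genes for 17 of 59 (41 adjusted over the list alone, median 0.21). Notch targets were lower for 2 of 21 and higher for 0 (8 lower and 1 higher adjusted over the list alone, median -0.26), and each of these lists had an adjusted p of 0.243 with an estimated correlation. Proneural genes (0 of 7, 0 adjusted over the list alone) had a median of -0.26 (adjusted p = 0.465 with an estimated correlation).

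Between scrib NAct and scrib RasV12 it differed for 202 genes (89 higher and 113 lower in scrib NAct), or 104 and 88 without scrib RasV12 library 1 or 2. It was higher in scrib NAct for dpn (log2 2.15 ± 0.13), E(spl)m8-HLH (2.14 ± 0.24), bib (2.05 ± 0.26) and E(spl)mgamma-HLH (2.04 ± 0.34), and lower for Pvf3 (-2.63 ± 0.36), Osi14 (-2.24 ± 0.24), aos (-2.12 ± 0.21) and vir-1 (-2.02 ± 0.22). Of 21 Notch targets 13 were higher and 1 lower (15 and 2 adjusted over the list alone, median 0.72). Of 40 cell cycle genes 10 were higher and 0 lower (18 and 0 adjusted over the list alone, median 0.21), each list with an adjusted p of 0.0916 with an estimated correlation. Of 26 EGFR, Ras and MAPK targets 2 were higher and 9 lower (4 and 12 adjusted over the list alone), with a median of -0.28 (adjusted p = 0.208 with an estimated correlation). JNK and stress response genes had a median of -0.19 (0 and 4 of 17, 1 and 7 adjusted over the list alone, adjusted p = 0.397 with an estimated correlation).

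Control 1 and scrib 1 stood apart from the other 6 libraries. Loss of scrib in the clones does not follow this split by design: scrib 1 and scrib 2 share it but lie on opposite sides. The root-mean-square log2 difference of 0.176 between scrib 1 and control 1 is part of the split itself, so it is no separate test. Another mix of male and female larvae is argued against, since 38.4% of scrib 1 cells and 50.3% of control 1 cells had a roX1 UMI. Both lie within the 31% to 54.1% of the other 6 libraries, although that range is wide. It runs from 31% and 32.7% in scrib RasV12 to 49.3% and 54.1% in scrib NAct, with scrib 2 at 48.4%. A difference between library batches remains open and untested, as the 0.395 between scrib 1 and scrib 2 is the split itself. No label gives a batch, and no other biological difference was tested.

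Cluster 19, which entered only the fits with all cells or with the unnamed clusters, held 4.97% of the scrib YkiS168A library (361 of its 380 cells), 0.242% of scrib library 2 (17 cells) and 0.018% of the control library. Its cells are argued against as GFP-marked clone cells, with GFP in 0.277% of them (upper bound 1.53%) and in 2.38% of epithelial-like cells matched on UMIs (1.73% to 3.2%). Shallow cells of the same larvae are argued against, since Gal80 was seen in 0.277% of them and in 9.25% of the matched cells (7.96% to 10.7%). Cells of animals without the GFP and Gal80 transgenes could account for it, as alphaTub84B, whose promoter drives Gal80, differed by a log2 of 0.01 (3037.5 against 3019.4 CPM), and this remains open. A roX1 UMI was seen in 83.1% of the cluster and 44.1% of epithelial-like cells. Nplp4 (71.3 against 0.76 CPM), Nplp2 (35.9 against 0.12) and twi (18.4 against 0.71) were higher in it, Mef2 (6.81 against 11.8) and elav (7.06 against 16.0) lower, and no biological explanation was tested.

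The rises of w and fs(1)K10 in scrib YkiS168A clone cells (log2 3.11 ± 0.32 and 2.75 ± 0.35, the latter from 4.93 to 39.0 CPM) are in a single library. For w, deeper clone cells are argued against, as w rose by 3.09 against comparators matched on UMIs, a value not read for fs(1)K10. Another mix of male and female cells is argued against, as roX1 was seen in 43.9% of clone cells and 44.2% of the others. Transcripts of the YkiS168A construct, which may carry w as its marker, remain open: the clone difference of w exceeded that in scrib by 2.93, and without reads construct and resident gene cannot be told apart. For fs(1)K10 it exceeded that in scrib by 2.59, and whether the construct holds fs(1)K10 sequence was not tested. Expression of YkiS168A itself, the biological difference in the design, also remains open and was not tested.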

How the results depend on the processing

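The batch term, the fits without or with named clusters, the matched and Gal80 comparators, the fit of 6 libraries, the left-out libraries and list tests in clone comparisons and all tests of clone differences between genotypes were chosen after the result was seen. Counts below are genes past the test under each alternative, and unless its construction shows it (fewer libraries, fewer UMIs) the cause was not tested. Leaving out the shallowest cells was not run, as the limit set for it lies below every cell (lowest 6049 UMIs), and scrib against control has no replicate block, as the control library's title gives no replicate number (the 1 in control 1 only names the library).

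For scrib against control the count was 1 as reported, 12 with no filter on low values, 3 with a mean of at least 20 CPM, 0 with the mean of natural-log values, 6 centred, 8 after quantile normalization, 3 in all cells, 0 without the variance trend, 5 with cells thinned to 2000 UMIs, 580 with the batch term, 4 with the unnamed clusters and 0 to 4205 leaving out libraries. For scrib NAct against scrib (603) it was 341 from summed UMIs, 1385 centred, 1589 after quantile normalization, 0 with only the compared groups, 308 with the replicate block, 353 thinned, 3046 with the batch term, 100 without the low-UMI clusters and 0 to 4166 leaving out libraries. For scrib RasV12 (1053) it was 698 from summed UMIs, 2130 centred, 2371 after quantile normalization, 296 with only the compared groups, 648 with the replicate block, 648 thinned, 3218 with the batch term, 442 without the low-UMI clusters and 0 to 4682 leaving out libraries. For scrib YkiS168A (11) it was 32 with no filter, 88 centred, 94 after quantile normalization, 0 without the variance trend, 0 with the replicate block, 17 thinned, 1211 with the batch term, 5 without the low-UMI clusters and 0 to 4067 leaving out libraries.

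With cells thinned to 2000 UMIs, the clone comparisons gave 0 (control, 34 as reported), 47 (scrib, 936), 44 (scrib NAct, 710), 54 (scrib RasV12, 923) and 0 (scrib YkiS168A, 406), so depth limits them. Without the GFP-rich cluster the counts were 495 (scrib), 396 (scrib NAct), 540 (scrib RasV12) and 225 (scrib YkiS168A). Control gave 22 with comparators matched on UMIs and 8 when matched on cluster and UMIs, scrib gave 405 against cells with a Gal80 UMI in the 6 libraries that list Gal80 (428 in those 6 against all cells without a GFP UMI, so most of the drop comes with leaving out scrib library 1), and scrib YkiS168A gave 253 with at least 2 GFP UMIs and 233 when matched on cluster and UMIs. Leaving out libraries gave 428 to 1057 (scrib), 356 to 655 (scrib NAct) and 426 to 982 (scrib RasV12), against 29 to 46 (control) and 362 to 459 (scrib YkiS168A).

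For the difference between scrib and control clones (184) the count was 0 thinned, 64 matched on cluster and UMIs and 75 without the GFP-rich cluster. Counts against Gal80 cells again rest on 6 libraries, and those for the same 6 against all cells without a GFP UMI are in brackets. For scrib NAct minus scrib (95) it was 2 thinned and 54 against Gal80 cells (64). For scrib RasV12 minus scrib (170) it was 70 with at least 2 GFP UMIs, 0 thinned, 50 matched on cluster and UMIs and 71 against Gal80 cells (42). For scrib YkiS168A minus scrib (152) it was 32 with at least 2 GFP UMIs, 0 thinned, 99 matched on UMIs, 44 matched on cluster and UMIs, 31 without the GFP-rich cluster and 68 against Gal80 cells (74). For scrib NAct minus scrib RasV12 (202) it was 92 with at least 2 GFP UMIs, 7 thinned and 101 matched on cluster and UMIs. Leaving out libraries gave 103 to 245 (scrib minus control), 64 to 106 (scrib NAct minus scrib), 29 to 227 (scrib RasV12 minus scrib), 74 to 200 (scrib YkiS168A minus scrib) and 88 to 191 (scrib NAct minus scrib RasV12).

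With an estimated correlation 0 lists were called in each of the 4 genotype and 5 clone comparisons. With fry 0, 8, 7 and 0 were called in the genotype comparisons (7, 15, 15 and 9 as reported) and 0 in control clones (5 as reported). Leaving out libraries gave 5 to 8 lists in control clones, 6 to 11 in scrib NAct (10 as reported) and 4 to 8 in scrib RasV12 (8 as reported).

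Among values of named genes under the alternatives, 2462 in clone comparisons stayed on the same side of the test, 469 fell short of it with the same sign and 3 changed sign. Those 3 were Arpc1 in scrib NAct clones (-0.27 thinned), Dr in scrib RasV12 clones (0.08 matched on cluster and UMIs) and nclb in scrib YkiS168A clones (-0.03 thinned). For clone differences between genotypes the numbers were 446, 129 and 1, the last E(spl)m4-BFM in scrib YkiS168A minus scrib (0.02 thinned). In the genotype comparisons 2358 values of genes past the test stayed past it and 718 fell short with the same sign, and of genes not past it 165 values stayed so and 41 passed.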

Other observations

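The counts of genes shared between genotypes and the genes named here were chosen after the result was seen, and no tests were planned for them.

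The 4 scrib genotypes shared many clone genes. In clone cells, 116 genes rose in all 4, against 0.0437 if the 4 sets were independent, and 5 of them also rose in control clones. Another 71 fell in all 4, against 0.0988, and 10 of them also fell in control clones. Control clones had only 15 rises and 19 falls in all, so these shared genes are a large part of the control calls. Control was a single library, so a gene not past the test there may still have changed. The 4 sets cannot be independent, because they come from the same fit, in which each gene has an error shared by all genotypes. Clone cells were also deeper than the other cells in every library. The expected numbers therefore cannot test whether the genotypes share genes, and no conclusion is drawn from them. Genes are not independent of each other either, and the comparators come from the same discs.

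Among the shared rises, the serpin gene Spn55B rose by log2 1.32 in scrib, 1.33 in scrib NAct, 1.40 in scrib RasV12 and 1.39 in scrib YkiS168A clones (-0.01 in control). The cytochrome P450 gene Cyp6a17 rose by 1.43, 1.49, 1.49 and 0.98 (0.23 in control), babos by 1.05, 0.91, 1.30 and 1.58 (-0.38 in control) and hid by 1.59, 1.42, 1.90 and 1.20 (0.38 in control). Ilp8 rose by 1.44, 2.92, 3.94 and 4.27 (-0.28 in control). Among the shared falls, Hsp67Ba was at -0.77, -0.90, -1.50 and -2.0 (-0.19 in control). The serine protease gene ea fell in the 4 scrib genotypes and in control clones alike (-0.87, -1.37, -1.33, -1.68 and -1.68).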
